A study of Homo sapiens with 2 samples.

How the data were processed

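The series measured single-cell RNA in 2 samples, here called the REH pool and the SUP-B15 pool after their leukaemia line. Each was a 10x Chromium 3' library of cells from 3 culture conditions (leukaemia by itself, called B-ALL alone; stroma by itself, called Niche alone; and both, called B-ALL-Niche), marked with 3 hashtag antibodies before pooling. Per the labels, cells were taken on day 7 after 45 min of nattokinase at 50 Fu/ml and 37 °C. The established lines REH and SUP-B15 and the osteoblast line hFOB are named in the labels, and the other niche cells are described there by type.

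The authors deposited a table of raw UMI counts for 20226 genes and 14650 cells, with no normalization. The deposited cell table gives each cell's total UMI count, its number of genes, the percent of its UMIs from mitochondrially encoded genes, its pool, its condition by hashtag, and 1 of 5 clusters named by the authors (REH, SUP, EC, MSC and Osteo). Per the file headers, the unfiltered droplet matrices hold raw UMI counts of all barcodes and were written by Cell Ranger software version 3.1.0. Deposited hashtag tables hold the count of hashtag UMIs per barcode. Per the submitters' processing notes, bcl2fastq, Cell Ranger and Seurat were used with builds hg38/GRCh38. Apart from that header, versions are not given in the sources used here. The rules by which the authors kept cells and genes, assigned hashtags and named clusters are not stated. The kept cells had 587 to 56747 UMIs, 450 to 6434 genes and at most 9.999 percent mitochondrial UMIs. A table of normalized values was left out because count tests need the raw UMIs. The column sums of the raw table were checked against the deposited totals, and 0 cells differed. XIST and Y-linked genes (19 names) were left out of every table, which leaves 20207 genes.

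Before the data were examined, the comparisons, the rule for naming genes, 25 gene lists, 8 marker sets and most alternatives were fixed. Raw counts were summed per pool, condition and cell class (leukaemia, endothelial, MSC-labelled, osteoblast-labelled), with all deposited cells of a class and condition. Leukaemia cells of the SUP-B15 pool were those in its own line's cluster. Per pool, the log2 ratio of CPM scaled by TMM (trimmed mean of M values) was given with an exact conditional binomial (Clopper-Pearson) 95% interval, for genes with at least 50 UMIs over both sums; a sum of 0 was set to 3 counts for a lower bound. These ratios rest on 1 sample per group and have no test. Over the pools, edgeR's quasi-likelihood test (filterByExpr, TMM, pool as a block, 4 sums and 1 residual degree of freedom) was run at a Benjamini-Hochberg adjusted p of 0.05. Its prior degrees of freedom were infinite in leukaemia and MSC-labelled cells, 10.4 in endothelial and 28.7 in osteoblast-labelled cells, so that the spread was largely pooled over genes. The common dispersions were 0.0302 in leukaemia, 0.00449 in endothelial, 0.00588 in MSC-labelled and 0.00506 in osteoblast-labelled cells.

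Named genes are those with at least 50 UMIs in each pool and at least 2-fold in the same direction in both pools with both intervals excluding 1, ranked by the smaller absolute log2 fold, the first 10 in each direction. Genes whose CPM in the pool's other cell kind was over 5 times that in the class itself were ranked apart, up to 5 per direction. Also named were members of the gene lists that passed the rule at 1.5-fold, up to 5 per list and comparison, and members with an edgeR adjusted p under 0.05.

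The lists cover the S and G2/M phases, cell cycle arrest, niche cytokines, cytokine receptors of leukaemia cells, adhesion, Notch pathway, NF-kB targets, interferon response, antigen presentation, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock and dissociation, p53 targets, apoptosis regulators, cholesterol synthesis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, MYC targets, pre-B cell identity, matrix, TGF-beta and contractile genes, osteogenic genes, and endothelial activation and angiogenesis. For each list the median log2 fold of its measured genes was placed among 10000 random lists, drawn for each member from the 100 genes nearest in expression. Marker sets were leukaemia, endothelial, mesenchymal stem cell, osteoblast, macrophage, erythroid, T cell and adipocyte. Class shares carry exact binomial intervals. Cell cycle shares are the percent of cells with at least 3 UMIs of G2/M genes after each cell was thinned to 2000 UMIs. Background RNA was estimated from barcodes with 1 to 100 UMIs, as the multiple of their profile that accounts for the UMIs of the other kind's markers in a class (leukaemia cells: mesenchymal stem cell markers; niche classes: leukaemia markers other than EBF1, which the mesenchymal classes also carry). Positions and Ensembl identifiers come from GENCODE 44 on GRCh38, which gave 280 of the 281 symbols sought.

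The fits were tested on simulated data with the fitted common dispersion and 200 changed genes. Each gene had 1 baseline for all 4 sums and the same fold in both pools. Differences between the pools were thus left out, so the recovery rates may not hold for these data. The counting intervals were checked on Poisson counts, where exact intervals hold at least 95% by construction. In the leukaemia comparison 34 percent of 2-fold and 98 percent of 4-fold genes were recovered, with 6 unchanged genes called, and 95.6% of the counting intervals held the simulated fold. For endothelial, MSC-labelled and osteoblast-labelled cells 98, 97 and 99 percent of 2-fold genes and all 4-fold genes were recovered, with 9, 4 and 11 unchanged genes called, and 95.7, 95.5 and 95.6 percent of the intervals held the fold. Alternatives fixed in advance were DESeq2 size factors, no gene filter, DESeq2's Wald test, no block, minimum counts of 20 and 100, fold minimums of 1.5 and 3, cells thinned to 2000 UMIs, a limit of 1% on the other kind's markers, an own-hashtag share of at least 80%, each pool left out, classes by the fixed markers, other thinning depths (1000, 4000 or none) and other G2/M minimums (1 or 5). Stricter limits on the other kind's markers (0.3% for leukaemia, 0.05% for niche cells), background subtraction, Niche alone of both pools as 1 sample, and leaving out cells with over 0.5% muscle gene UMIs were chosen after seeing the data. The fit with Niche alone as 1 sample had no pool block. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.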

Results

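Single-cell RNA of a cultured model of the leukaemic bone marrow was counted in 2 pools, each of which was 1 run of droplet sequencing with hashtag antibodies. The pools were named for their leukaemia cells. REH and SUP-B15 are established B cell precursor acute lymphoblastic leukaemia (B-ALL) lines, REH with the ETV6-RUNX1 fusion and SUP-B15 with the BCR-ABL1 fusion. Each pool held 3 conditions that the hashtags told apart: the leukaemia cells alone (B-ALL alone), the stromal cells alone (Niche alone), and the leukaemia cells with the stromal cells (B-ALL-Niche). Per the labels, the niche was made of human umbilical vein endothelial cells, mesenchymal stem cells (MSC) and the fetal osteoblast line hFOB, and cells were released from the gel with nattokinase on day 7 of culture. Every condition thus had 1 sample per pool. The labels do not say whether the Niche alone samples of the pools were separate cultures. The p-values below rest on a spread between these samples only, largely pooled over genes. In leukaemia and MSC-labelled cells, where the prior degrees of freedom were infinite, a gene's own spread did not enter. A gene with opposite folds in the pools could thus be called.

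The deposited table held 14650 cells and 234218038 unique molecular identifiers (UMIs). The REH pool had 8420 cells with a median of 12323 UMIs per cell and 122920780 UMIs in all, and the SUP-B15 pool had 6230 cells with a median of 16900 and 111297258 UMIs in all. Leukaemia cells were shallower in SUP-B15 (median 3821 UMIs per cell in B-ALL alone and 2801 in B-ALL-Niche) than in REH (9329 and 10492). Endothelial, MSC and osteoblast classes had medians of 11361 to 21158 UMIs per cell in the sums compared below. Pairs of log2 folds are given with the REH pool before the SUP-B15 pool, with 95% exact binomial (Clopper-Pearson) counting intervals, which cover counting error only.

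The mixture under each hashtag was counted first. Leukaemia cells made up 98.0% of the 1052 B-ALL alone cells (97.0 to 98.8) and 78.8% of the 4397 B-ALL-Niche cells (77.6 to 80.03) in the REH pool. In the SUP-B15 pool they made up 85.3% of 722 cells (82.5 to 87.8) and 3.77% of 2945 cells (3.11 to 4.52), which left 111 SUP-B15 leukaemia cells in the niche. Under the Niche alone hashtag, leukaemia cells were 0.841% of 2971 cells in the REH pool and cells of the SUP-B15 cluster were 0 of 2563 cells in the SUP-B15 pool, which allows a share of up to 0.117% (3 counts of the total), besides 3 cells in the REH cluster. Among niche cells of the REH pool, endothelial cells were 21.8% in Niche alone and 20.5% in B-ALL-Niche, MSC 40.8% and 41.5%, and osteoblasts 37.4% and 38.0%. In the SUP-B15 pool endothelial cells were 22.7% in Niche alone (21.1 to 24.4) and 15.2% in B-ALL-Niche (13.9 to 16.6). Osteoblasts were 35.5% (33.7 to 37.4) and 44.2% (42.3 to 46.0) there, and MSC 41.8% and 40.6%. With at least 80% of hashtag UMIs in the own tag, endothelial cells were 14.7% and 14.4% and osteoblasts 42.0% and 44.7%. These differences in SUP-B15 thus depended on the hashtag limit. The limit removed 281 of 581 endothelial and 51 of 910 osteoblast-labelled cells of Niche alone, and 31 of 431 endothelial cells of B-ALL-Niche. It fell unevenly on the classes, so it does not show which shares are right. All deposited cells were kept and no doublets were called, so cells with transcripts of both kinds count in these shares. The cells of B-ALL alone had a median of 75.3% of their hashtag UMIs in their own tag in the REH leukaemia class and 87.4% in the SUP-B15 one, and with a minimum of 80% the SUP-B15 leukaemia share under that tag was 98.2%. RNA at the profile of empty droplets was estimated at 4.73% and 5.19% of the UMIs of REH leukaemia cells in B-ALL alone and B-ALL-Niche, and at 11.5% and 14.6% in SUP-B15.

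**Figure D1:**
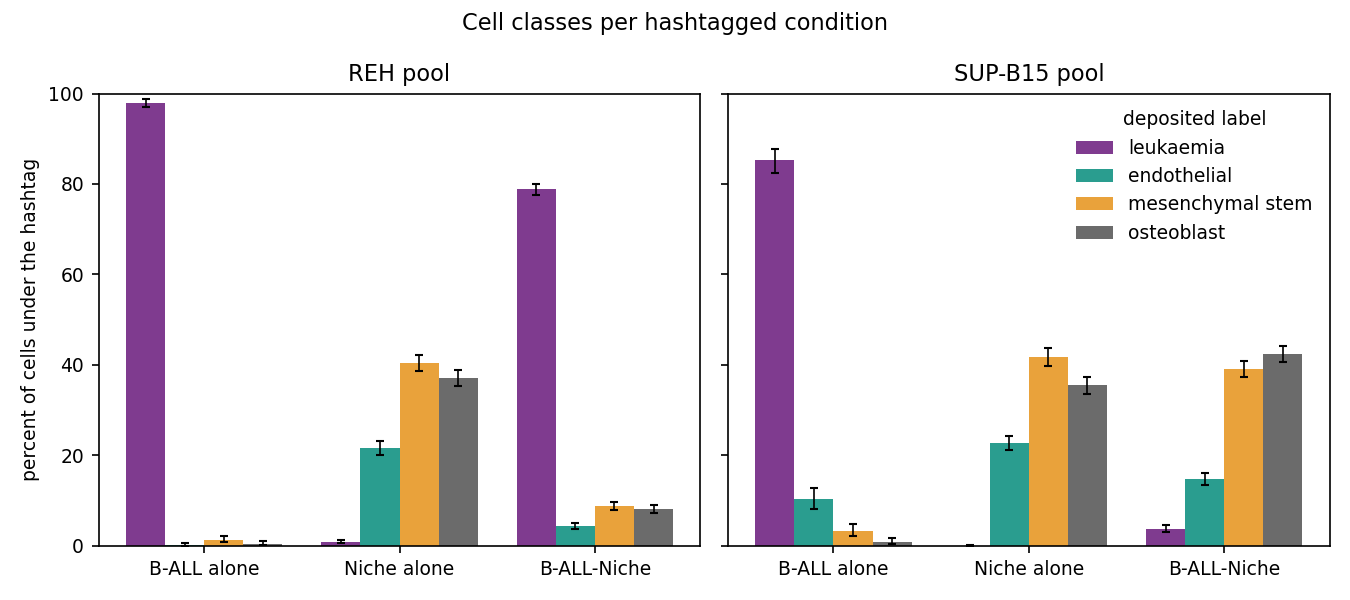
Percent of cells (vertical axis) in each of the 4 cell classes under each hashtag condition (horizontal axis) in each pool, with bars from 0 and lines for the 95% exact binomial intervals. Leukaemia cells were 78.8% of the B-ALL-Niche cells in the REH pool and 3.77% in the SUP-B15 pool.

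The deposited names of the MSC and osteoblast classes did not follow the fixed marker genes. In Niche alone, DCN, which encodes the collagen-binding proteoglycan decorin and was listed as an MSC marker, had 43.5 and 39.7 CPM (UMIs scaled to a common total) in the class labelled MSC and 530 and 527 CPM in the class labelled osteoblast. COL1A1, encoding type I collagen, had 1095 and 945 CPM against 3508 and 3100 CPM, and the osteoblast transcription factor gene RUNX2 had 19.9 and 19.1 CPM in the class labelled MSC against 8.41 and 10.5 CPM in the class labelled osteoblast. Of the 12 MSC markers measured, 10 were higher in the class labelled osteoblast in both pools, and of the 6 osteoblast markers measured, 4 were higher in the class labelled MSC. The classes are therefore called here by the authors' labels, MSC-labelled and osteoblast-labelled cells. Leukaemia markers (15 genes) reached 3695 and 5032 CPM in the leukaemia cells of B-ALL alone against 16.1 to 98.5 CPM in the Niche alone classes. Endothelial markers (13 genes) reached 1799 and 1671 CPM in endothelial cells against 33.1 to 51.9 CPM in the other Niche alone classes. Macrophage markers (3 genes) were at 14.6 to 74.4 CPM in the Niche alone classes, of which CD68 gave 14.3 to 73.5 CPM. Adipocyte markers were at 0.135 to 3.98 CPM there, and none of the erythroid markers was in the table. T cell markers (2 genes) reached 153 and 178 CPM in endothelial cells of Niche alone, of which IL32 gave 148 and 174 CPM. The macrophage and T cell sums thus rested mostly on CD68 and IL32, and they do not show that such cells were present.

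Because each pool has 1 sample per condition, the Niche alone samples of both pools gave a yardstick for folds between single samples. At a minimum of 50 UMIs over both sums, 62 of 10297 genes in endothelial cells, 98 of 12839 in MSC-labelled cells and 82 of 12195 in osteoblast-labelled cells differed by at least 2-fold between the pools. B-ALL-Niche against Niche alone gave 115 and 52 such genes in endothelial cells (REH pool, then SUP-B15 pool), 116 and 206 in MSC-labelled cells and 141 and 184 in osteoblast-labelled cells. Endothelial cells of the SUP-B15 pool thus had fewer 2-fold genes by condition than Niche alone had between pools. The yardstick crosses 2 runs, while the folds by condition lie within 1 run. It also holds leukaemia background, with leukaemia markers at 92.8 and 16.1 CPM in endothelial cells of Niche alone (REH pool, then SUP-B15 pool). The lower count therefore does not show that the condition had no effect there.

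Leukaemia cells grown with the niche were compared with the same line grown alone, to ask which genes differ when B-ALL cells share a culture with marrow stroma. CD69 (ENSG00000110848, chromosome 12, 9752486 to 9760901 on GRCh38), an early activation antigen of lymphocytes, had log2 folds of 2.85 (2.59 to 3.13) and 4.31 (3.76 to 4.88), from 11.6 to 83.6 CPM in the REH pool and from 13.6 to 269 CPM in the SUP-B15 pool. It rose with an edgeR log2 fold of 3.46 (SE 0.259) and an adjusted p of 1.9e-36. Interferon response genes were higher in both lines: IFI44L (ENSG00000137959, chromosome 1, 78619902 to 78646145) by 2.58 (2.12 to 3.07) and 4.12 (3.46 to 4.81), and MX1 (ENSG00000157601, chromosome 21, 41420020 to 41470071), whose product blocks viral replication, by 2.02 (1.79 to 2.26) and 4.13 (3.67 to 4.62). Of the 30 interferon response genes tested by edgeR, 15 rose, and 22 rose when adjusted over the list alone. The median log2 fold of the 20 measured members was 0.62 and 1.79, at percentiles 100 and 100 of random lists matched on expression. With cells thinned to 2000 UMIs the list medians were 0.53 and 0.95. Members with smaller folds in REH included the transcription factor gene IRF7 (0.78 and 2.52) and the ubiquitin-like modifier gene ISG15 (0.42 and 1.90). Not every member was higher in both lines. SAMD9 went from 43.8 to 26.3 CPM in REH, and LY6E from 62.1 to 58.5 CPM in SUP-B15. The antiviral sensors OAS1 and OAS2 had folds of 1.89 and 3.62 and 1.03 and 3.16, and IFITM1 and IFITM3, which block virus entry, of 1.26 and 1.73 and 0.83 and 0.90.

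Other genes at 2-fold in both pools were GADD45B (1.85 and 2.39), a stress-induced growth arrest gene, the AP-1 subunit gene JUNB (1.72 and 1.65), the stress-induced transcription factor gene ATF3 (1.19 and 1.65) and TNFAIP3 (1.43 and 1.72), an inhibitor of NF-kB signalling. PLSCR1, an interferon-induced phospholipid scramblase gene, had folds of 1.16 and 1.77 and rose with an adjusted p of 2.5e-05, whereas the fructose transporter gene SLC2A5 (1.27 and 1.23) did not pass the test (adjusted p = 0.29). HIST1H1B, a replication-dependent linker histone gene, was lower by -1.21 (-1.33 to -1.08) and -4.32 (-9.63 to -1.82), the second from 1 UMI in B-ALL-Niche, and the histone chaperone gene DNAJC9 was lower by -1.03 and -1.77. Among NF-kB targets (medians 0.21 and -0.08) 3 of 23 rose, 8 up and 1 down adjusted over the list alone, with those that rose including the apoptosis inhibitor gene BIRC3 (2.39 and 1.29) and CD40 (1.66 and 0.76). Of the unfolded protein and amino acid stress genes, ATF3 and DDIT3 (1.18 and 0.96) rose, 6 adjusted over the list alone, with list medians of 0.46 and 0.20 at percentiles 100 and 97.7 (0.095 in SUP-B15 after thinning to 2000 UMIs). Heat shock and dissociation genes split, with medians of 0.92 and -0.24: JUNB, IER3, FOS (1.99 and 0.64) and JUN (2.18 and -0.08) rose and the heat shock gene HSPA1A (0.59 and -2.71) fell in the test, 5 up and 5 down adjusted over the list alone. For JUN and HSPA1A the sign depended on the pool.

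Antigen presentation genes had medians of 0.03 and 0.85: HLA-E (0.90 and 0.90) and the class II transactivator gene CIITA (0.73 and 1.88) rose, and 11 of 21 did adjusted over the list alone. MYC (0.90 and 1.33) and, among pre-B cell genes, the surrogate light chain gene VPREB3 (2.07 and 0.40) rose. Mitochondrially encoded transcripts were slightly lower, with medians of -0.24 and -0.20 at percentiles 0 and 0.92, and MT-ND2 (-0.69 and -0.56) and MT-ND5 (-0.40 and -0.85) fell, 6 of 13 adjusted over the list alone. Lists with medians inside the central 95% of random lists in both pools were the regulators of apoptosis (-0.04 and -0.07), oxidative phosphorylation (-0.07 and -0.21), ribosomal proteins (0.13 and 0.26), cell cycle arrest (0.06 and 0.09), Notch pathway (0.04 and 0.05) and niche cytokines (0.12 and 0.36). Cytokine receptors had medians of 0.21 and 0.17, adhesion genes 0.22 and 0.19, p53 targets 0.00 and 0.29, cholesterol synthesis genes 0.19 and -0.46 and hypoxia and glycolysis genes 0.22 and -0.09. After thinning, the cytokine receptor median in REH was 0.024 and the cholesterol synthesis medians were 0.090 and -0.97. Genes typical of stroma, which in leukaemia droplets are exposed to background RNA, had medians of 0.17 and 0.25 (matrix; -0.21 in SUP-B15 after thinning), 0.04 and 0.37 (TGF-beta and contractile; -0.17 in SUP-B15 after thinning and -0.080 after background subtraction), 0.20 and -0.94 (osteogenic, 3 genes) and 0.51 and -0.04 (endothelial activation, 5 genes).

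In all, edgeR's quasi-likelihood test with the pool as a block called 94 of 12645 genes, 62 higher and 32 lower, at a Benjamini-Hochberg adjusted p of 0.05, and 16 of 6958 measured genes passed 2-fold in both pools (14 higher, 2 lower, 12 of them called). DESeq2's test called 8 genes, edgeR without the block 0 (14 genes at an unadjusted p under 0.05), and edgeR after thinning all cells to 2000 UMIs 5. Subtracting the background profile, an alternative added after seeing the data, left 8 calls.

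**Figure D2:**
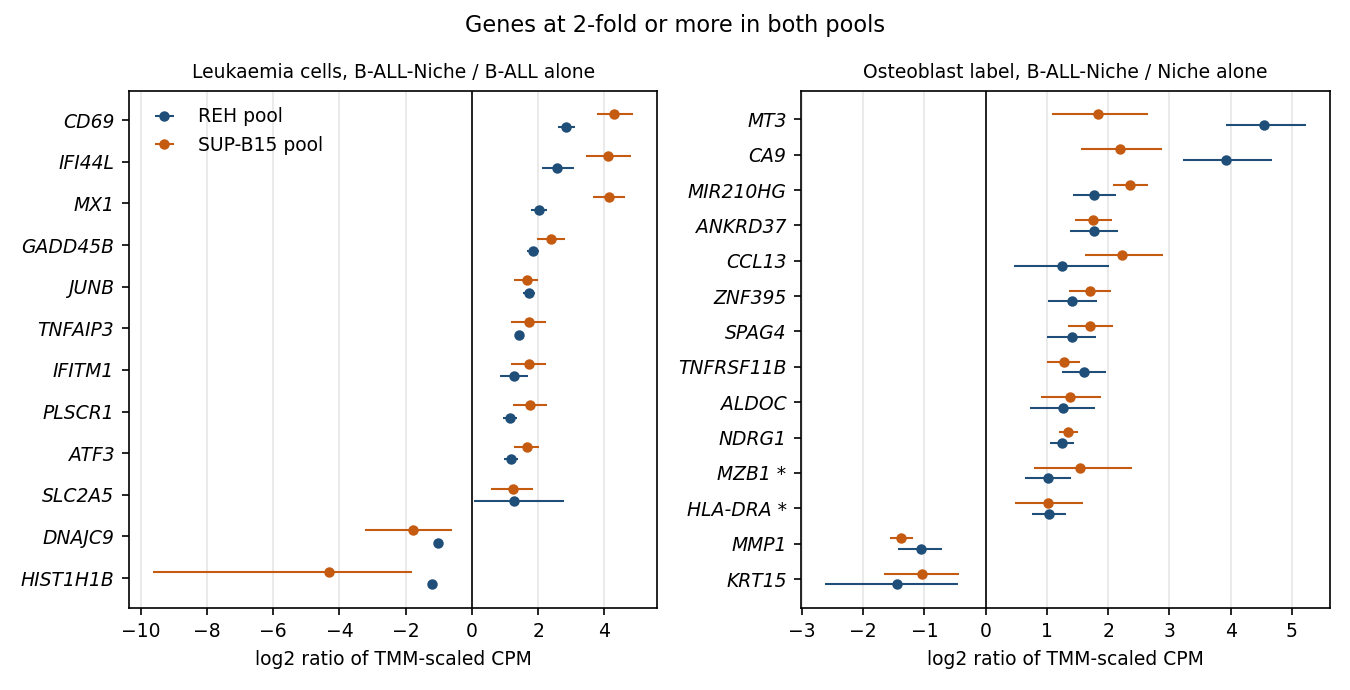
Log2 folds (horizontal axis) of the genes named by the 2-fold rule (vertical axis) in leukaemia cells, B-ALL-Niche over B-ALL alone, and in osteoblast-labelled cells, B-ALL-Niche over Niche alone. Markers are the pools, lines the 95% counting intervals, and an asterisk marks genes abundant in the other cell kind. CD69 lies at 2.85 and 4.31 in leukaemia cells and CA9 at 3.92 and 2.19 in osteoblast-labelled cells.

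Proliferation genes were then followed in the leukaemia cells. In SUP-B15 they were lower in the niche: MKI67 (the Ki-67 antigen gene; -0.33 and -2.40), CENPF (a kinetochore protein gene; -0.23 and -2.04), TOP2A (topoisomerase II alpha; 0.22 and -2.04) and TYMS (thymidylate synthase; -0.05 and -2.59), while REH stayed between -0.33 and 0.22. All 4 fell in the edgeR test with adjusted p-values of 2.5e-05, 2.5e-05, 0.04 and 0.0067. For TOP2A the sign depended on the pool. The G2/M list had medians of 0.17 and -1.44 with 3 of 54 genes lower in the test and 5 adjusted over the list alone, and the S phase list had -0.02 and -0.90 with TYMS lower either way. G2/M genes took 0.949% of REH UMIs in B-ALL alone (0.943 to 0.955) and 0.984% in B-ALL-Niche (0.981 to 0.987), against 0.610% (0.601 to 0.619) and 0.274% (0.258 to 0.291) in SUP-B15. S phase genes took 0.632% and 0.622% in REH and 0.227% and 0.133% in SUP-B15. After thinning to 2000 UMIs per cell, 95.4% of 1021 REH cells in B-ALL alone and 96.5% of 3453 in B-ALL-Niche had at least 3 G2/M UMIs, and in SUP-B15 62.8% of 576 and 55.7% of 88. The ratio of the SUP-B15 shares was 0.886 (0.728 to 1.08) with 23 of the 111 B-ALL-Niche cells too shallow to count, and 0.575 with thinning to 1000 UMIs, so it depended on the depth chosen. Endothelial cells, the class with the lowest share of such cells, had 42.1% to 50.2% at the same depth.

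The lines were set beside each other to see how far their responses overlapped; with 1 sample per line and condition this has no test, and line cannot be told from run. Of 6958 genes measured in both, 16 moved by at least 2-fold the same way and 10 in opposite directions. Another 79 passed in REH alone and 458 in SUP-B15 alone. Passing also needed a counting interval that excluded 1. A gene could therefore miss it in the other line through few UMIs as well as through a smaller change. Over all genes measured in each pool by itself, 598 moved by at least 2-fold in REH and 511 in SUP-B15. Across genes, which are not independent replicates, the folds of the lines had a Pearson r of 0.0744 and a Spearman rho of 0.0673. Counting error in the shallow SUP-B15 sum of B-ALL-Niche (381186 UMIs) pulls such correlations towards 0. They therefore do not measure how unlike the responses were. The lines differed far more from each other than by condition: 3490 of 10547 genes were at least 2-fold apart in B-ALL alone (1476 higher in SUP-B15, 2014 lower) and 2919 of 12344 in B-ALL-Niche. The interleukin 7 receptor gene IL7R was lower in SUP-B15, with log2 folds over REH of -4.69 (-5.11 to -4.30) in B-ALL alone and -4.20 (-5.20 to -3.36) in B-ALL-Niche. ITGA6, the laminin receptor subunit gene, was higher by 7.63 (6.87 to 8.51) and 6.47 (6.06 to 6.88), and the cytokine receptor subunit gene IL6ST by 3.73 and 3.48. VPREB1, of the surrogate light chain, had 0 UMIs in REH and 817 in SUP-B15 cells of B-ALL alone. The survival gene BCL2 was lower in SUP-B15 by -1.64 (-2.00 to -1.30) and -3.04 (-4.49 to -1.92). Interferon-induced IFITM3 was higher in SUP-B15 by 3.63 and 3.62 in the conditions, whereas MX1, which stood 0.26 (-0.21 to 0.71) apart in B-ALL alone, was 2.29 (2.03 to 2.55) higher in SUP-B15 in B-ALL-Niche.

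Endothelial cells with leukaemia were compared with those of Niche alone. The monocyte chemoattractant gene CCL2 (ENSG00000108691, chromosome 17, 34255274 to 34257208) rose, with log2 folds of 2.25 (2.02 to 2.49) and 0.84 (0.58 to 1.12) and an edgeR log2 fold of 1.61 (adjusted p = 0.03). TNFAIP3 (0.84 and 0.92), the class I antigen gene HLA-B (0.62 and 0.56), the endoplasmic reticulum chaperone gene PDIA4 (0.49 and 0.49), ANKRD1, a target of mechanical and TGF-beta signals (0.62 and 0.66), and the proteoglycan gene BGN (0.43 and 0.61) rose too, with adjusted p-values from 0.013 to 0.03. QPRT, of NAD synthesis, was the sole gene at 2-fold in both pools that was not abundant in leukaemia cells (1.34 (0.70 to 1.96) and 1.32 (0.52 to 2.16)), and did not pass the test (adjusted p = 0.096). Antigen presentation genes had medians of 0.36 and 0.25 (0.20 and 0.38 after thinning to 2000 UMIs). Of 19 such genes 4 rose, 10 adjusted over the list alone. Of the 4, HLA-DRA, CD74 and HLA-DQB1 were abundant in leukaemia cells, which leaves HLA-B. Unfolded protein genes had 0.35 and 0.13 with 1 of 19 up, 5 adjusted over the list alone. Niche cytokines (0.23 and 0.21) and TGF-beta and contractile genes (0.12 and 0.33) also lay above the central 95% of random lists in both pools, with CCL2 and ANKRD1 up and, adjusted over the list alone, 5 genes up and 1 down in the former and 6 up in the latter. After background subtraction the TGF-beta median in REH was -0.050. Mesenchymal stem cell markers in endothelial droplets went from 297 to 395 CPM in the REH pool and from 398 to 622 CPM in the SUP-B15 pool. Only leukaemia cells counted as the other kind here. Rises of matrix and contractile genes such as BGN and ANKRD1 were therefore not separated from RNA of the other niche classes. NF-kB targets had medians of 0.67 and 0.05 (0.31 in REH after thinning), interferon response genes -0.58 and -0.02 (-0.21 in REH after thinning), endothelial activation genes -0.18 and -0.06, heat shock genes 0.19 and -0.17 and matrix genes -0.10 and 0.28.

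Leukaemia transcripts rose in the same endothelial droplets: HLA-DRA (2.02 and 3.17), CD74 (1.81 and 2.34), DNTT (1.32 and 2.06), the DNA polymerase of lymphocyte precursors, and from the lists HLA-DQB1 (4.56 and 4.53), CD79A (1.93 and 1.91) and IGLL1 (1.77 and -0.01), the last in the REH pool alone, while PAG1 (1.15 and 1.91) and RCSD1 (1.14 and 1.91) did not pass the test. The estimated background share of endothelial UMIs was 6.06% in Niche alone and 15.3% in B-ALL-Niche of the REH pool, and 2.26% and 7.02% in the SUP-B15 pool. Leaving out endothelial cells with over 0.05% leukaemia marker UMIs, a limit added after seeing the data, turned the fitted log2 folds of HLA-DRA, CD79A and IGLL1 to -0.01, -0.12 and -0.39. CD79A and IGLL1 are among the markers that set this limit, so their change follows from it. edgeR called 18 of 11938 genes (15 higher, 3 lower). It called 0 with that limit (701 at an unadjusted p under 0.05), 0 without the block (584), 0 after background subtraction (585), and DESeq2 called 3.

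MSC-labelled cells with leukaemia carried more RNA of hypoxia-linked, matrix and growth arrest genes and less of interferon genes. MIR210HG (ENSG00000247095, chromosome 11, 565657 to 568457), host gene of the hypoxia-induced microRNA miR-210, rose by 2.31 (1.90 to 2.74) and 1.80 (1.503 to 2.11) with an edgeR log2 fold of 2.02 (SE 0.16, adjusted p = 3.8e-32). NDRG1, a stress and hypoxia-induced gene, rose by 1.28 (0.97 to 1.60) and 1.06 (0.81 to 1.32). Of the 29 hypoxia and glycolysis genes, 13 rose and 17 did adjusted over the list alone, with medians of 0.30 and 0.35, of which the SUP-B15 one was 0.056 after thinning to 2000 UMIs. Among them were CA9, encoding a carbonic anhydrase induced by HIF-1 (2.71 and 1.66), BNIP3 (0.55 and 0.58), the collagen hydroxylase gene P4HA1 (0.55 and 0.66) and ADM (0.83 and 0.45). Interferon response genes were lower, with medians of -0.77 and -0.23: 18 of 30 fell, 22 adjusted over the list alone, with MX1 (-1.49 and -0.68), OAS1 (-1.03 and -0.60), IFIT1 (-1.31 and -0.42) and ISG15 (-0.90 and -0.27) among them. Matrix genes had medians of 0.21 and 0.46, and 16 of 27 rose (21 up and 2 down adjusted over the list alone), among them COL3A1 (0.44 and 0.98), LUM (0.35 and 1.07) and DCN (0.46 and 0.92). Of the growth arrest genes 7 of 20 rose, 8 adjusted over the list alone, including the thioredoxin inhibitor gene TXNIP (0.73 and 0.64) and the CDK inhibitor genes CDKN1A (0.32 and 0.38) and CDKN1C (0.34 and 0.75). MYC targets had medians of -0.18 and -0.34 and 9 of 24 fell, 16 adjusted over the list alone, among them the polyamine synthesis gene ODC1 (-0.31 and -0.81).

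Other MSC-labelled genes at 2-fold in both pools were CHI3L1 (1.26 and 1.10), a secreted chitinase-like protein gene, OLFM2 (1.26 and 1.16), TENM2 (1.17 and 1.53), DMBT1 (1.19 and 1.18), the long noncoding RNA AC104794.2 (1.24 and 1.17) and the muscle precursor transcription factor gene PAX7 (1.02 and 1.30), all of which rose. CELA3A (-2.51 and -1.03), a pancreatic protease gene, fell. Among niche cytokines 9 of 25 rose and 1 fell (11 up and 3 down adjusted over the list alone): CCL5 (0.92 and 1.68) and CCL2 (0.96 and 0.69) rose and CXCL5 (-1.41 and -0.66) fell. CXCL12, the chemokine that holds B cell precursors in the marrow, rose in the test with opposite signs in the pools (-0.32 and 1.08). G2/M genes had medians of -0.06 and -0.33 and 7 of 54 fell, 12 adjusted over the list alone. Of the p53 targets 5 of 20 rose (8 adjusted over the list alone; medians 0.07 and 0.26), of the unfolded protein genes 4 of 20 by either count (0.12 and 0.08). The Notch pathway had medians of 0.12 and 0.32 (0.24 and 0.28 after thinning) with 3 of 18 up adjusted over the list alone. Pre-B cell genes had medians of 0.41 and 0.54 over 11 measured genes (0.013 in REH after thinning). Niche cells carry some genes of that list themselves, such as CD9 and SOX4 (up to 137 and 91.9 CPM in Niche alone). The list thus mixes such genes with leukaemia RNA. The background share of UMIs was 4.50% and 6.61% in the REH pool and 2.15% and 3.02% in the SUP-B15 pool.

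For MSC-labelled cells edgeR called 603 of 14813 genes (396 higher, 207 lower), DESeq2 46, and edgeR without the block 4, while 9 of 12155 measured genes passed 2-fold in both pools, all of them called. Treating the Niche alone cells of both pools as 1 sample, an alternative added after seeing the data, left 4 calls. That fit also had no pool block, so its result is not separated from the loss of the block. Thinning to 2000 UMIs left 85.

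Osteoblast-labelled cells showed the widest hypoxia-linked shift. CA9 (ENSG00000107159, chromosome 9, 35673928 to 35681159) rose by 3.92 (3.23 to 4.67) and 2.19 (1.56 to 2.88) (edgeR log2 fold 3.08, SE 0.288, adjusted p = 1.5e-08), the metallothionein gene MT3 by 4.54 and 1.83, MIR210HG by 1.78 and 2.35 and ANKRD37 by 1.78 and 1.75. The glycolytic aldolase gene ALDOC (1.26 and 1.38), NDRG1 (1.25 and 1.35), SPAG4 (1.41 and 1.70) and ZNF395 (1.41 and 1.70) rose with them. Of 28 hypoxia and glycolysis genes tested, 18 rose, 23 adjusted over the list alone, with medians of 0.42 and 0.69. SLC2A1, the main glucose transporter gene, rose by 1.00 and 1.13, BNIP3 by 0.83 and 1.14, PGK1 by 0.60 and 0.58 and the angiogenic factor gene VEGFA by 0.39 and 0.99. Endothelial activation and angiogenesis genes had medians of 0.43 and 0.27, and 6 of 21 rose (7 adjusted over the list alone; medians 0.099 and 0.17 after thinning), including the ligand genes APLN (1.98 and 2.46) and PGF (0.73 and 1.32). TNFRSF11B (ENSG00000164761, chromosome 8, 118923557 to 118951885), encoding the decoy receptor osteoprotegerin that restrains osteoclasts, rose by 1.61 (1.25 to 1.96) and 1.27 (1.00 to 1.55), and the chemokine gene CCL13 by 1.24 and 2.23. The collagenase gene MMP1 (ENSG00000196611, chromosome 11, 102789401 to 102798160) fell, with log2 folds of -1.06 (-1.43 to -0.71) and -1.37 (-1.56 to -1.19) (adjusted p = 1.7e-08), as did KRT15 with -1.44 and -1.04.

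Interferon response genes fell in osteoblast-labelled cells as well, 18 of 30 (21 adjusted over the list alone), with medians of -0.55 and -0.45 and examples MX1 (-1.11 and -0.82), IFIT1 (-0.77 and -0.70) and ISG15 (-0.95 and -0.51). Among niche cytokines (0.44 and 0.12) 8 of 25 rose, 10 adjusted over the list alone: CCL20 (1.16 and 1.05) and IL6, a growth factor gene of B lineage cells (0.79 and 0.93), in both pools, and CXCL8 (1.05 and -0.04) and CXCL1 (1.53 and -0.14) in the REH pool with values just below 0 in SUP-B15. Matrix genes had medians of 0.21 and 0.46; 17 of 27 rose and MMP1 fell (23 and 1 adjusted over the list alone), with the cross-linking enzyme gene LOX (0.58 and 0.58) and COL1A1 (0.29 and 0.53) among those that rose. Osteogenic genes had medians of 0.28 and 0.36 (2 of 13 up, 3 adjusted over the list alone). S phase genes had medians of -0.12 and -0.39 (-0.34 and -0.44 after thinning to 2000 UMIs). Of 44 such genes 6 fell (11 adjusted over the list alone), among them the helicase gene MCM5 (-0.43 and -0.60) and CLSPN (-0.57 and -0.63). Of 24 MYC targets 6 fell and LDHA rose (13 and 1 adjusted over the list alone). Arrest genes (0.27 and 0.21; 7 of 20 up, 8 adjusted over the list alone), NF-kB targets (0.20 and 0.28; 4 of 22 up, 8 adjusted over the list alone), heat shock and dissociation genes (0.13 and 0.15; 9 up and 2 down of 20, 10 and 4 adjusted over the list alone; -0.055 in REH after thinning), p53 targets (0.15 and 0.13) and adhesion genes (0.12 and 0.15) also lay above the central 95% of random lists. Antigen presentation genes (0.11 and 0.21) did too, with 4 up and 1 down of 20 (8 and 4 adjusted over the list alone), but HLA-DRA (1.03 and 1.02), like MZB1 (1.02 and 1.55), was abundant in leukaemia cells. The adhesion median in REH was 0.028 after thinning. Pre-B cell genes had medians of 0.55 and 0.38 (0.041 and 0.26 after thinning), and the background share was 4.37% and 7.02% in the REH pool and 1.80% and 3.28% in the SUP-B15 pool.

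edgeR called 540 of 14029 genes in osteoblast-labelled cells (381 higher, 159 lower), and 28 of 11635 measured genes passed 2-fold in both pools, 27 of them called. DESeq2 called 91, edgeR without the block 34, with Niche alone as 1 sample (also without the block) 34, and after thinning 178.

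**Figure D3:**
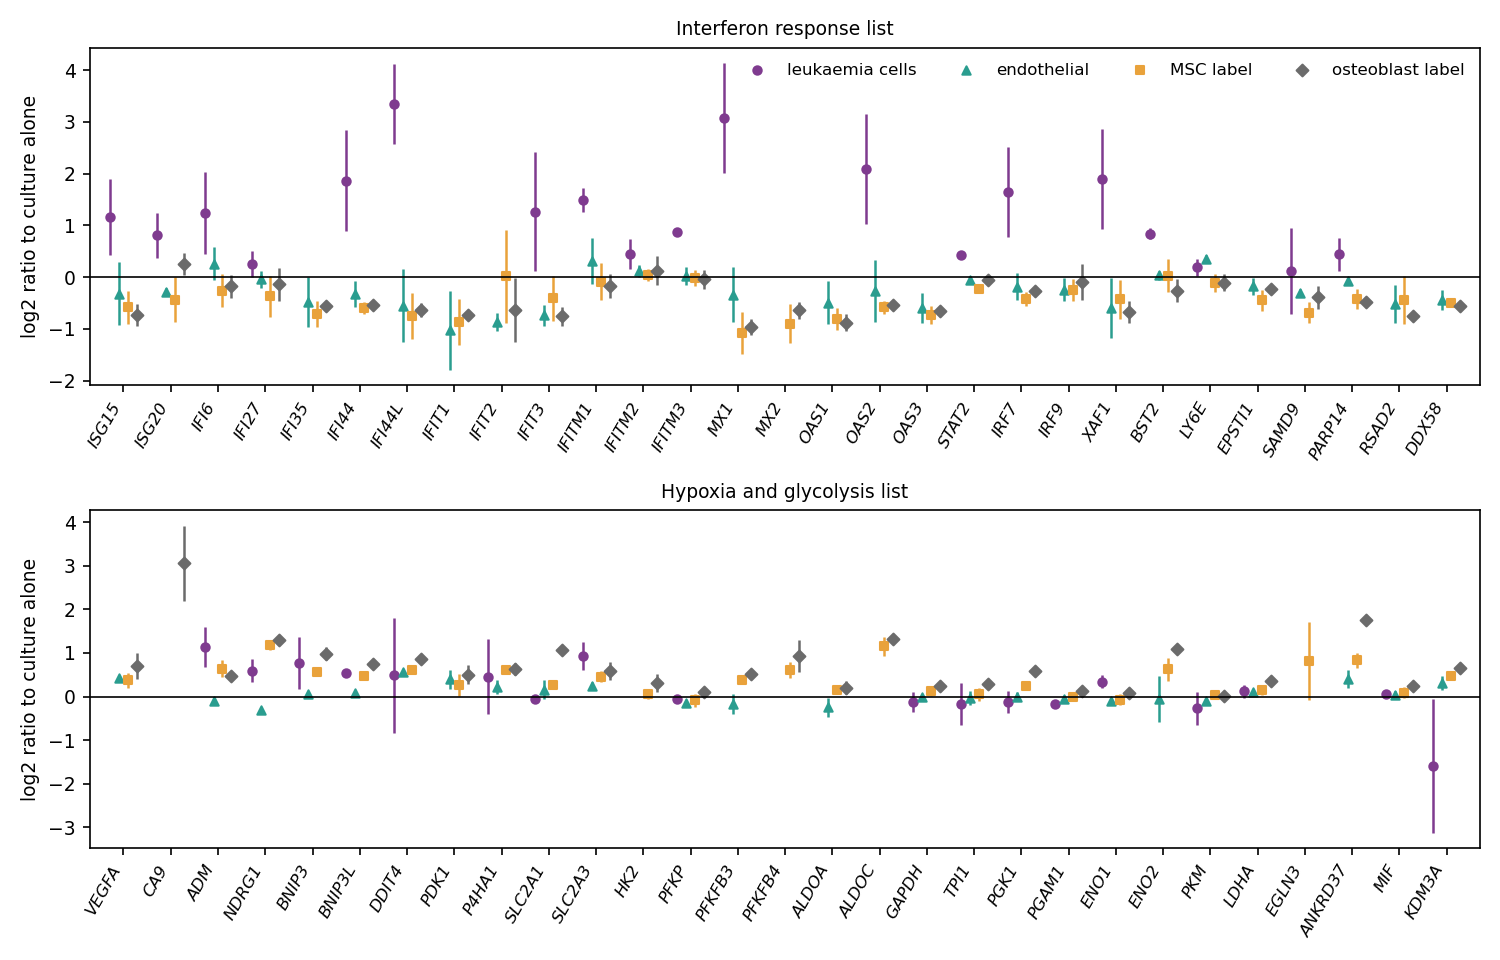
Log2 folds (vertical axis) of most of the measured interferon response and hypoxia and glycolysis genes (horizontal axis) in the 4 cell classes, B-ALL-Niche over the culture without the other cell kind; markers are the mean of both pools and lines reach from one pool's value to the other's. MX1 was at 2.02 and 4.13 in leukaemia cells, -1.49 and -0.68 in MSC-labelled cells and -1.11 and -0.82 in osteoblast-labelled cells.

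**Figure D4:**
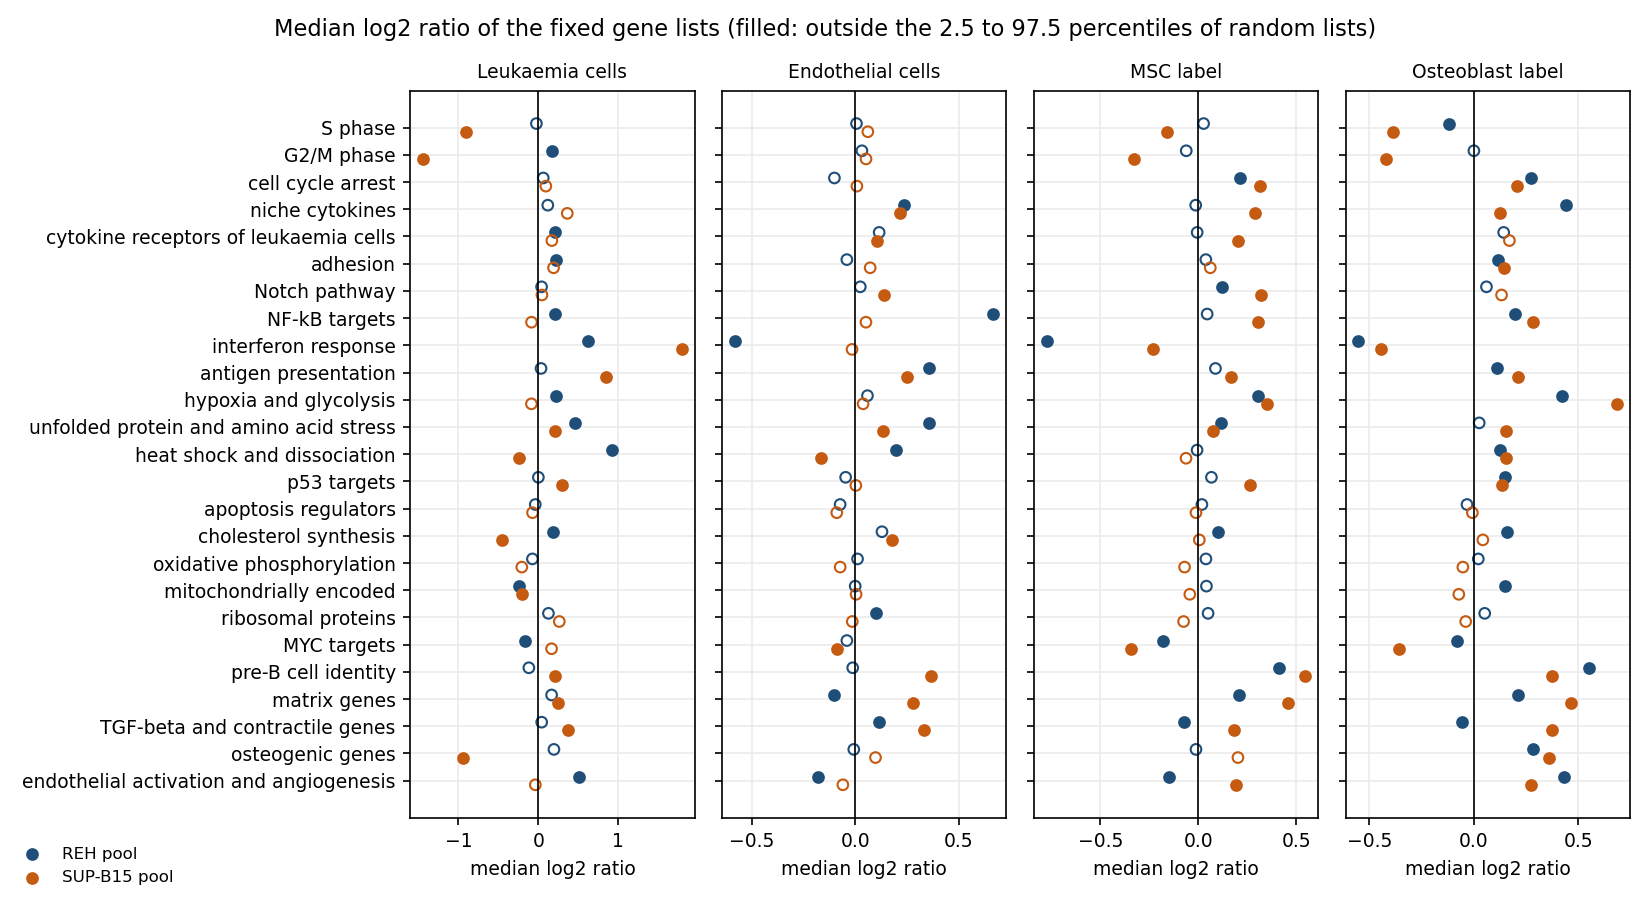
Median log2 fold of each of the 25 gene lists (vertical axis) in the 4 classes and both pools (horizontal axis in log2 units); filled markers lie outside the central 95% of random lists of genes of like expression. Beyond those percentiles and higher in both pools were 2, 4, 6 and 12 lists in leukaemia, endothelial, MSC-labelled and osteoblast-labelled cells.

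Cell cycle genes of niche cells were counted in the same way as in the leukaemia cells. After thinning, 59.8% of osteoblast-labelled cells in Niche alone of the SUP-B15 pool had at least 3 G2/M UMIs (56.5 to 63.0) and 44.6% in B-ALL-Niche (41.8 to 47.4), a ratio of 0.746 (0.688 to 0.810). In the REH pool the shares were 61.7% and 55.9% and the ratio 0.906 (0.817 to 1.00). MSC-labelled cells had ratios of 0.940 (0.884 to 0.999) and 0.894 (0.854 to 0.935), from 81.8% to 76.9% and from 81.7% to 73.0%. Endothelial cells had 0.841 (0.698 to 1.01) and 1.01 (0.868 to 1.16), from shares of 50.2% and 42.1% in Niche alone. G2/M genes took 0.327% of the UMIs of osteoblast-labelled cells of the SUP-B15 pool in Niche alone and 0.240% in B-ALL-Niche, against 0.322% and 0.313% in the REH pool. Without thinning the SUP-B15 osteoblast ratio was 1.00, since nearly every cell then held 3 such UMIs.

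Signals known to bind or feed leukaemia cells were located among the niche classes in Niche alone. Of 45 ligand and adhesion genes measured, 7 were highest in endothelial cells in both pools, 7 in MSC-labelled and 24 in osteoblast-labelled cells, and for 7 the highest class differed between pools. IL6 had 59.9 and 66.9 CPM in osteoblast-labelled cells, 10.8 and 11.03 in MSC-labelled and 4.15 and 6.07 in endothelial cells, against 1.96 CPM in REH and 2.63 CPM (1 UMI, 0.0665 to 14.6) in SUP-B15 leukaemia cells of B-ALL-Niche. CXCL12 was low in every class, at 11.6 and 9.38 CPM in MSC-labelled and 13.0 and 11.96 CPM in osteoblast-labelled cells (0.389 and 0.809 in endothelial cells). VCAM1, the ligand of the integrin VLA-4, had 64.0 and 65.3 CPM in osteoblast-labelled cells, 7.91 and 7.67 in MSC-labelled and 1.69 and 4.72 in endothelial cells. IL7 had 2.28 and 1.77 CPM in osteoblast-labelled cells. Among genes highest in endothelial cells were ICAM1 (69.0 and 58.4 CPM) and BMP4 (37.4 and 40.5), and among those highest in MSC-labelled cells IL11 (15.7 and 16.8) and SPP1, which encodes osteopontin (10.1 and 7.95). ITGA4, the VLA-4 alpha chain gene, had 148 and 215 CPM in leukaemia cells of B-ALL-Niche.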

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

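Of the tests below, leaving out the leukaemia cells richest in interferon transcripts and thinning to 2000 UMIs were chosen before their results were seen, and the others (niche RNA in leukaemia droplets, leaving out cells by all measured interferon members, dilution of stromal droplets, muscle-rich cells, RNA outside cells and the exchange of labels) were chosen after, the one on RNA outside cells in place of a ratio of log2 folds that had no value in the REH pool, and the one on niche RNA in place of a form limited to the 9 members at 1.5-fold in both pools.

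Interferon response genes were higher in leukaemia cells of B-ALL-Niche (medians 0.62 and 1.79) and lower in the MSC-labelled (-0.77 and -0.23) and osteoblast-labelled cells (-0.55 and -0.45) of the same cultures. Niche RNA in leukaemia droplets was argued against in SUP-B15. There the share needed for the rise of the 20 measured members was at the median 9.973 times the share that mesenchymal markers showed (quartiles 5.45 and 18.6). In REH the test was undecided, with a median of 3.371 and quartiles of 1.37 and 11.1 around the bound of 3. It set the rise against the whole niche share in B-ALL-Niche, 3.18% in REH, and not against its gain. In REH leukaemia droplets the mesenchymal markers were already at 216 CPM in B-ALL alone, against 237 CPM in B-ALL-Niche. The lower quartile of the need was 4.36%, above that whole share. With 1 sample per condition, this argues against niche RNA in REH too, except for the 4 members that needed at most that share. A few strongly responding cells were argued against too: without the top 5% of cells (174 and 6) at least 82.7% of the log2 ratio remained, 0.75 of 0.91 in REH and 1.41 of 1.53 in SUP-B15 for the 9 members at 1.5-fold in both pools, and 68.6% and 91.7% over all 20. Dilution of stromal droplets by leukaemia RNA would need at least 10.86 times the share that leukaemia markers other than EBF1 showed (14.9% to 41.5% needed, 0.351% to 2.93% shown). With every cell thinned to 2000 UMIs the medians kept their signs (0.53 and 0.95 in leukaemia, -0.58 and -0.17 in MSC-labelled, -0.62 and -0.38 in osteoblast-labelled cells), with SUP-B15 leukaemia falling from 1.79, while differences between single cultures were not tested, so the explanation stays open.

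Skeletal muscle genes moved in opposite directions in MSC-labelled cells, a difference that was not tested. MYH3, an embryonic myosin gene, had log2 folds of -4.58 and 3.58, ACTA1 -4.75 and 2.71, TTN -4.41 and 2.30 and MYL1 -4.36 and 2.76. They were among 19 genes at 2-fold or more that fell on opposite sides in the pools. Of the 19, 12 were in a list of 20 muscle genes. That list was not among those fixed in advance, so the number is no independent support. RNA outside cells was argued against, because the summed CPM of these genes was at least 4.188 times higher in MSC-labelled than in osteoblast-labelled cells (240 against 12.7 CPM in Niche alone of the REH pool). A small group of muscle-like cells, caught unevenly, cannot be told apart from a change across the class: 89 of 3805 cells (2.34%) held a median of 65.71% of the UMIs of the 7 opposite genes outside the list, between the bounds of 50% and 80% set for the test. Such cells went from 1.58% in Niche alone to 2.07% in B-ALL-Niche in the REH pool and from 1.59% to 3.92% in the SUP-B15 pool. The summed CPM of the 12 listed genes went from 240 to 32.5 in the REH pool and from 138 to 619 in the SUP-B15 pool. In REH the share of muscle-rich cells thus did not follow that fall. The 7 genes outside the list include the heat shock gene HSPA6, which moved the reverse way (1.05 and -1.11). Without the muscle-rich cells edgeR called 664 genes instead of 603, and no biological explanation was tested.

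The deposited MSC and osteoblast labels ran against the fixed markers in Niche alone, where 10 of 12 MSC markers (83.3%) were higher in the class labelled osteoblast and 4 of 6 osteoblast markers in the class labelled MSC. The smaller of these shares, 66.67%, lay below the 75% that an exchange of the labels was taken to need, and POSTN, FBLN1 and PHEX were among the markers that followed the labels, so an exchange of the names cannot be told apart from cells that changed in culture. The class labelled MSC had more CDKN2A (597 and 604 CPM against 87.0 and 89.4) and more of the muscle determination gene MYOD1 (24.3 and 20.4 against 0.290 and 0.443), genes chosen after their values were seen. No table holds a reference profile of either cell source, which keeps the question open, and no biological explanation was tested.

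In leukaemia cells 10 genes moved by at least 2-fold in opposite directions in the lines, a difference that was not tested, among them the heat shock genes HSPA1B (1.97 and -4.75) and HSPB1 (1.17 and -1.08), the phosphodiesterase gene PDE4B (-1.38 and 4.05) and MME, which encodes CD10 (-1.45 and 1.195). These 4 leukaemia genes were picked out after their values were seen. In osteoblast-labelled cells 2 did so, untested: KLRD1 (-1.21 and 1.30) and TTN (-1.15 and 1.40). The next list medians had opposite signs outside the percentiles of random lists in the pools, and none of these differences was tested. In leukaemia cells these were G2/M genes (0.17 and -1.44), heat shock genes (0.92 and -0.24) and cholesterol synthesis genes (0.19 and -0.46). After thinning to 2000 UMIs these medians were 0.16 and -1.02, 0.76 and -0.48, and 0.090 and -0.97. In endothelial cells they were heat shock (0.19 and -0.17) and matrix genes (-0.10 and 0.28). In MSC-labelled cells they were TGF-beta and contractile genes (-0.072 and 0.18) and endothelial activation genes (-0.15 and 0.19, but 0.23 and -0.068 after thinning to 2000 UMIs), and in osteoblast-labelled cells TGF-beta and contractile genes (-0.056 and 0.37, with REH at 0.12 after thinning and 0.0082 after background subtraction).

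Some cells lay under a hashtag whose culture should not hold their class and entered no comparison. Under B-ALL alone of the SUP-B15 pool were 74 endothelial, 23 MSC-labelled and 6 osteoblast-labelled cells. Those endothelial cells had a median of 14234 UMIs and 63.5% of their hashtag UMIs in their own tag, leukaemia markers (here without EBF1, which stromal cells carry too) at 929 CPM against 14.8 CPM in endothelial cells of Niche alone, and endothelial markers at 1417 against 1671 CPM. Under B-ALL alone of the REH pool were 14 MSC-labelled, 5 osteoblast-labelled and 2 endothelial cells. Under Niche alone of the REH pool were 25 leukaemia cells, with a median of 15552 UMIs, leukaemia markers without EBF1 at 1032 CPM and mesenchymal markers at 3430 CPM, against 3266 and 237 CPM in leukaemia cells of B-ALL-Niche. In the SUP-B15 pool 10 cells lay in the REH cluster, 3 in B-ALL alone, 4 in B-ALL-Niche and 3 in Niche alone.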

How the results depend on the processing

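Stricter limits on the other kind's markers, background subtraction, Niche alone as 1 sample and the removal of muscle-rich cells were chosen after seeing the data, and the other alternatives before. Of the values that answer a comparison, 132 under alternatives fixed in advance and 18 under added ones stayed within their spread or within 1.5 times the count, 110 and 11 moved, and 1 reversed. For single genes and list medians 2403 and 723 values kept their side, 777 and 358 kept their direction but no longer passed the threshold, 41 and 32 moved, and 24 and 7 reversed. Fold minimums, count minimums, thinning and left-out pools alter how many genes can pass, which accounts for part of these moves by construction. Otherwise the cause was not tested. Likewise, the 1% limit on the other kind's markers removed 1 REH leukaemia cell of B-ALL-Niche and no other cell of the sums compared. Values that stayed the same under that limit thus did so by construction.

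Genes called by the test, from 94 in leukaemia, 18 in endothelial, 603 in MSC-labelled and 540 in osteoblast-labelled cells, came to 8, 3, 46 and 91 with DESeq2's test. Without the pool block they came to 0 (14 at an unadjusted p under 0.05), 0 (584), 4 and 34, and after thinning to 2000 UMIs to 5, 30, 85 and 178. With no gene filter 161 endothelial genes were called. With an own-hashtag share of at least 80% the calls were 72 in endothelial and 304 in MSC-labelled cells. Stricter limits on the other kind's markers gave 55 in leukaemia and 0 in endothelial cells (701 at an unadjusted p under 0.05 in edgeR, where DESeq2 on all cells called 3). Background subtraction gave 8 in leukaemia, 0 in endothelial (585 at an unadjusted p under 0.05) and 390 in MSC-labelled cells. Niche alone of both pools as 1 sample gave 0 in endothelial (220 at an unadjusted p under 0.05), 4 in MSC-labelled and 34 in osteoblast-labelled cells. That fit had no pool block either, and its calls were as many as without the block alone.

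Genes at 2-fold in both pools, 16, 7, 9 and 28 in leukaemia, endothelial, MSC-labelled and osteoblast-labelled cells, came to 75, 28, 76 and 114 at 1.5-fold, to 5, 2, 1 and 4 at 3-fold, and to 9, 0, 1 and 7 after thinning. At least 20 counts gave 14 endothelial and 19 MSC-labelled genes, and at least 100 counts gave 1 and 4. The stricter marker limit left 1 endothelial gene. With 1 pool left out, the counts in the other ranged from 511 to 598, 52 to 115, 116 to 206 and 141 to 184. For Niche alone between pools, 62 endothelial, 98 MSC-labelled and 82 osteoblast-labelled genes became 183, 229 and 216 at 20 counts, 11, 37 and 36 at 100 counts, 226, 251 and 226 at 1.5-fold, 22, 51 and 50 at 3-fold, and 28, 25 and 13 after thinning. For the lines' responses, opposite genes (10) became 5 at 100 counts, 54 at 1.5-fold, 2 at 3-fold and 4 after thinning. Genes that passed in REH alone (79) became 137 at 20 counts, 330 at 1.5-fold, 17 at 3-fold and 46 after thinning. Those that passed in SUP-B15 alone (458) became 290 at 100 counts, 774 at 1.5-fold, 196 at 3-fold and 268 after thinning.

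Lists above the central 95% of random lists in both pools came after thinning to 1, 2, 2 and 5 (from 2, 4, 6 and 12), to 1 in leukaemia cells with DESeq2 size factors, and to 2 in endothelial cells after background subtraction, which also put 1 endothelial list below it (from 0). Members past 1.5-fold in both pools (22, 8, 13 and 29) became 8, 3, 1 and 9 at 2-fold and 103, 62, 155 and 185 at any size.

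Shares of leukaemia cells in B-ALL alone became 100% (REH) and 98.2% (SUP-B15) with an own-hashtag share of at least 80%, 98.9% (REH) with at least 2000 UMIs, and 80.9% (SUP-B15) by the fixed markers. They became 0.293% in Niche alone of the REH pool with the hashtag minimum and 3.02% in B-ALL-Niche of the SUP-B15 pool with at least 2000 UMIs. Under the hashtag minimum endothelial cells were 19.8% and 14.7% of niche cells in Niche alone and osteoblast-labelled cells 39.3% and 42.0% (REH pool, then SUP-B15 pool). By the fixed markers MSC were 78.9% and 78.4% in Niche alone and 80.7% and 85.7% in B-ALL-Niche, and osteoblasts 0.0341% and 0% in Niche alone and 0% and 0.106% in B-ALL-Niche. The ratio of G2/M shares in leukaemia cells was 1.05 (REH) and 0.575 (SUP-B15) with thinning to 1000 UMIs. In endothelial cells of the REH pool it was 1.03 with at least 5 G2/M UMIs, and in osteoblast-labelled cells of the REH pool 1.01 without thinning. In MSC-labelled cells of the SUP-B15 pool it was 0.836 at 1000 UMIs, 0.957 at 4000, 0.9997 without thinning, 0.983 with at least 1 and 0.846 with at least 5 G2/M UMIs. In osteoblast-labelled cells of the SUP-B15 pool it was 0.638, 0.878, 0.933 (at least 1) and 0.645 (at least 5), and it reversed to 1.0045 without thinning, where 99.2% and 99.7% of cells passed.

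With 1 pool left out, the log2 fold of the other pool was taken, with no new fit. Genes called by the test whose log2 folds had opposite signs in the pools are given as ranges over the pools. In leukaemia cells they were TOP2A -2.04 to 0.22, JUN -0.084 to 2.18 and HSPA1A -2.71 to 0.59. In MSC-labelled cells they were CXCL12 -0.32 to 1.08, CXCL2 -0.089 to 0.87, TNFAIP3 -7.6e-05 to 0.89, IFI27 -0.78 to 0.031, IFIT3 -0.84 to 0.016, EGLN3 -0.086 to 1.71, ZFP36 -0.11 to 0.84, SOX4 -0.061 to 0.76 and POSTN -0.28 to 0.92. In osteoblast-labelled cells they were CXCL8 -0.037 to 1.05, CXCL1 -0.14 to 1.53 and THBS1 -0.025 to 1.12. The stricter marker limit reversed the fitted log2 folds of HLA-DRA (-0.011), CD79A (-0.12) and IGLL1 (-0.39) in endothelial cells. It also reversed HLA-DRA (-0.10) in MSC-labelled cells. CD79A and IGLL1 are among the markers that set the limit. Thinning reversed VCAM1 in MSC-labelled cells (-0.17) and CDCA3 (0.24) and DNTT (-0.12) in osteoblast-labelled cells. It also reversed list medians: in leukaemia cells of the SUP-B15 pool matrix genes to -0.21 and TGF-beta and contractile genes to -0.17, in MSC-labelled cells endothelial activation genes to 0.23 (REH) and -0.068 (SUP-B15), and in osteoblast-labelled cells of the REH pool heat shock genes to -0.055 and TGF-beta genes to 0.12. Background subtraction put the TGF-beta list at -0.080 in leukaemia cells of the SUP-B15 pool, -0.050 in endothelial cells of the REH pool and 0.0082 in osteoblast-labelled cells of the REH pool.

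Depth limits the leukaemia comparison: the 111 SUP-B15 cells of B-ALL-Niche held 381186 UMIs against 38253647 in REH, so genes of low expression had fewer than 50 UMIs over both sums there and were not measured. Each condition had 1 sample per pool, and the test's spread came from 4 sums with 1 residual degree of freedom and was pooled over genes.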

Other observations

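The edgeR test and the gene lists used here were fixed in advance, but the grouping of the genes below was chosen after their values were seen. FOS, an AP-1 subunit gene, and ATF3 rose in both stromal classes. FOS had log2 folds of 0.76 and 1.07 in MSC-labelled and 0.80 and 1.34 in osteoblast-labelled cells, and ATF3 had 0.46 and 0.44 in the former and 0.55 and 0.79 in the latter. All 4 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p-values from 4.5e-08 to 0.0018. The chaperone genes HSPA8 and HSPH1 fell, by log2 folds of -0.32 and -0.37 and of -0.30 and -0.48 in MSC-labelled and of -0.34 and -0.27 and of -0.27 and -0.34 in osteoblast-labelled cells. Some members of the TGF-beta and contractile list rose in osteoblast-labelled cells: CYR61 (0.46 and 0.50) and TGFBI (0.34 and 0.61) in both pools, ID2 by 0.22 and 0.85 and CTGF by 0.02 and 0.69. Of 19 genes of that list 6 rose, adjusted over all genes or over the list alone, but the list medians had opposite signs (-0.056 in the REH pool, below the central 95% of random lists, and 0.37 in the SUP-B15 pool, above it). The REH median turned to 0.12 after thinning and to 0.0082 after background subtraction. HEY1, a Notch target gene, fell (-0.83 and -0.49), and the adhesion genes ICAM1 (0.95 and 0.43) and VCAM1 (0.55 and 0.19) rose. In MSC-labelled cells ESM1, a proteoglycan gene of activated endothelium, fell (-0.99 and -0.78), and the elastin gene ELN rose (0.77 and 3.16). CSF1, the macrophage growth factor gene, rose there too (0.33 and 0.67), as did the growth factor gene ANGPT1 in MSC-labelled (0.16 and 1.01) and osteoblast-labelled cells (0.45 and 0.57).

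The lines carried different surface antigens and precursor genes, in values with 1 sample each and no test. CD22 was lower in SUP-B15 than in REH, with log2 folds of -2.44 (-2.96 to -1.96) in B-ALL alone and -2.39 (-3.70 to -1.34) in B-ALL-Niche, and CD38 by -2.35 and -3.98. CD9 was higher by 3.23 and 4.87 and the B cell transcription factor gene IKZF1 by 1.34 and 1.64. The recombinase gene RAG1 was lower in SUP-B15 in B-ALL alone (-1.68, from -1.92 to -1.44) and level with REH in B-ALL-Niche (-0.08, from -0.46 to 0.28). Of the class II antigen genes HLA-DRA went from -1.14 (-1.24 to -1.05) to -0.06 (-0.22 to 0.10) and HLA-DPA1 from -1.41 to -0.38. HLA-DPB1 went from -0.38 to 1.05 and HLA-DQB1, already higher in SUP-B15 in B-ALL alone (1.496), to 2.48. The chemokine receptor gene CXCR4 went from -1.59 (-1.83 to -1.36) to -0.31 (-0.68 to 0.04). CD34, a stem and progenitor antigen, had 0 UMIs in REH and 416 in SUP-B15 cells of B-ALL alone. The survival genes MCL1 and BCL2L1 stood 0.83 (0.61 to 1.04) and 0.01 (-0.30 to 0.32) apart there. In B-ALL-Niche these 2 genes stood -0.44 (-1.11 to 0.17) and -0.05 (-0.89 to 0.67) apart.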
